A study of Homo sapiens with 9 samples.

How the data were processed

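RNA from MCF7 cells was sequenced in 9 libraries, 3 each from cells given DMSO, AZD4573 for 4 h and AZD4573 for 8 h, and groups and replicate numbers were taken from the labels. Per the labels' protocols, poly(A) RNA was enriched with oligo(dT) beads, copied into cDNA from random hexamers, made into libraries with an NEBNext Ultra mRNA kit and sequenced paired-end. The labels also call the DMSO group untreated and list 0 h among the treatment times, so the controls may not match the treated cells in time. The strand setting, the concentration of the drug and any culture or day shared by libraries are not given in the sources used here.

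The deposited table holds estimated counts per gene symbol, not normalized, for 58157 genes, with 1 column per library and 0 columns without a sample. Per the submitters' processing notes, the authors used HISAT2 2.0.5, FastQC, edgeR and limma with hg38 (GRCh38), without the role of each. The program that made the estimated counts and its annotation are not given in the sources used here. The deposited values are mostly not whole: 0.08% of those above 0 were whole (tolerance 1e-09), and 57.2% of those above 0 and under 20 were a whole number plus 0.01 (tolerance 0.001). How reads of overlapping or near-identical genes were shared out is unknown, so such genes are uncertain. In 28 rows the symbol reads as a date, as spreadsheet software leaves it. These rows held 0.173% of all counts and were kept as unnamed genes (2 of the date names stand on more than 1 row).

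Estimated counts were rounded to whole numbers before any count test. The test chosen before the data were examined assumed whole counts, and rounding is the only departure from it. The choice of tests, named genes, lists and alternatives was also fixed at that point, apart from those said to be later. Library totals ran from 26717074 to 34219517 counts. On counts simulated at these depths with 200 genes changed, the test called 55.2% of 2-fold changes at 4 h (19774 genes), 62.7% at 8 h (19776 genes) and 59.7% for 8 h against 4 h (19775 genes), and 86.4%, 83.3% and 87.9% of 4-fold changes. Of the 140, 140 and 143 calls made there, 7.14%, 7.86% and 5.59% were of unchanged genes. Floors and depths cover counting error only, since reads amplified by PCR carry no molecular identifier. Replicates of a group differed by more than sampling noise, with a chi-square per gene of 4.61 to 41.3, so each counted as 1 sample.

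Genes were kept with edgeR's filterByExpr, which left 19809. Counts were scaled by TMM and fitted in edgeR 4.0.16 (R 4.3.3) with the quasi-likelihood model, 1 mean per group, all 9 libraries and no block. The 3 comparisons were 4 h with DMSO, 8 h with DMSO and 8 h with 4 h, at a Benjamini-Hochberg adjusted p under 0.05. Levels are TMM-scaled CPM as mean ± SD. Standard errors of log2 fold changes were derived from the test statistic. The 2-fold counts add a bound on the fitted fold change to the adjusted p. Principal components used log2 CPM.

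The 29 gene lists were tested in each comparison with camera (limma 3.58.1, preset correlation 0.01, at least 5 tested members, adjustment over the lists of a comparison), and again with a correlation estimated from the data and with fry, which tests against no change. They cover survival and pro-apoptotic genes, immediate early genes, P-TEFb, RNA polymerase II, Mediator, estrogen receptor, p53 and NF-kB targets, G1/S, G2/M, homologous recombination, ribosome biogenesis, ribosomal proteins, mitochondrial mRNAs, oxidative phosphorylation, histones, ZNF genes, small nucleolar RNA hosts, heat shock, unfolded protein response, interferon, sterol synthesis, glycolysis, epithelial genes, fibroblast and haematopoietic markers, nuclear long noncoding RNAs and the spliceosome. In addition, 3 sets came from gene structure: protein-coding genes with a single exon, and the longest and shortest by genomic span. Rows were matched by symbol to GENCODE 29 on GRCh38, 35586 directly and 988 through a synonym. A gene with counts of 0 in a whole group was placed at 3 counts over the group where a bound was needed.

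Named genes were 15 fixed ones, the 6 largest rises and 6 largest falls against DMSO and the 5 and 5 between the times. These had to be protein-coding, pass the test, average at least 4 on the log2 CPM scale and show no overlap between the libraries of both groups. From each list, members with the smallest adjusted p at either time were named, and any other gene was chosen after its values were seen.

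The overlap of both DMSO comparisons was set beside 20 sets of simulated unchanged groups against the same DMSO libraries and beside independent lists. The alternatives were RLE, upper-quartile, library-total, ribosomal protein and mitochondrial scaling, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, fits of the libraries compared only, the replicate number as a block, and leaving out each library. After seeing the data, the single-exon set was also tested without histones, and then against 5 multi-exon genes per gene matched on GC content, transcript length and level in DMSO (2000 bootstrap resamples). Shared sequence was searched with blastn 2.17.0+ (at least 100 bases at 90% identity). Tables and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.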

Results

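MCF7 is an established human breast cancer line that expresses the estrogen receptor. Its cells were exposed to AZD4573, an inhibitor of the kinase CDK9, for 4 h or 8 h, or to DMSO, the vehicle. CDK9 is the catalytic subunit of P-TEFb, the complex that releases paused RNA polymerase II into productive elongation. Poly(A)-selected RNA was sequenced from 3 libraries in each of 3 groups, 9 libraries in all, and read as an estimated count per gene symbol. The comparisons ask which transcripts differed from DMSO at each time and how levels moved between 4 h and 8 h. The drug concentration is not given in the sources used here, and the DMSO libraries carry no time of their own, so each comparison with DMSO holds the drug and any effect of time in culture together. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

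Library totals were 30398709, 34219517 and 33282979 counts for DMSO, 31265255, 31453524 and 28465579 at 4 h, and 31544652, 32410878 and 26717074 at 8 h. In principal components of log2 CPM, PC1 held 74.7% of the variance and ordered the libraries from DMSO through 4 h to 8 h. Replicate 2 at 4 h lay nearer to the 8 h libraries (PC1 score 43.1) than replicates 1 (16.9) and 3 (14.2). Mitochondrially encoded mRNAs took 3.75% ± 0.363 of all counts in DMSO, 6.88% ± 0.295 at 4 h and 7.81% ± 0.876 at 8 h (SD, n = 3). Cytosolic ribosomal protein mRNAs took 5.47% ± 0.125, 7.35% ± 0.495 and 9.45% ± 0.286 in the same groups, and the 10 most abundant genes 5.44% ± 0.257, 8.85% ± 0.167 and 10.5% ± 0.436.

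**Figure D1:**
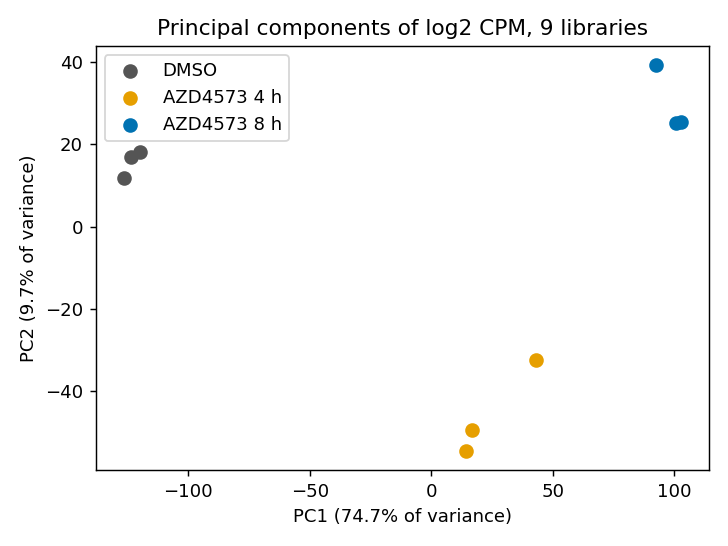
Scores of the 9 libraries on PC1 (x axis, 74.7% of the variance) and PC2 (y axis, 9.71%) of log2 CPM, one point per library, coloured by group. The 3 groups separate along PC1, and replicate 2 at 4 h, at 43.1 on PC1, stands between the other 4 h libraries and those at 8 h.

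RNA-seq counts give levels relative to the rest of a library, so every direction below is relative to the typical transcript, which TMM scaling places near a log2 fold change of 0. The median over all 19809 tested genes was -0.02 at 4 h, -0.08 at 8 h and -0.02 from 4 h to 8 h. Scaling by library totals moved that median to -0.39, -0.73 and -0.30, ribosomal protein mRNAs as the reference moved it to -0.81, -1.51 and -0.66, and mitochondrial mRNAs as the reference moved it to -1.27, -1.79 and -0.47. These are called the ribosomal protein and the mitochondrial reference, or both reference sets. Upper-quartile scaling moved it to 0.11, 0.19 and 0.12. No spike-in is named in the sources used here, and the total amount of mRNA per cell was not measured.

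**Figure D2:**
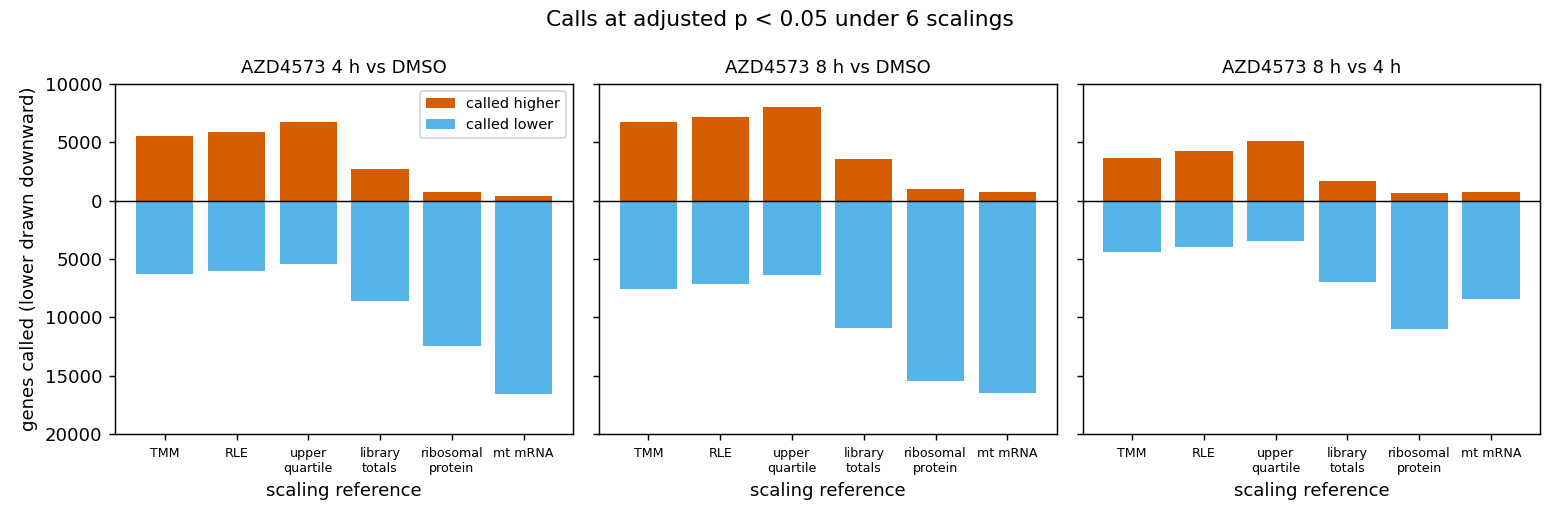
Genes called higher (upward bars) and lower (downward bars) at adjusted p under 0.05 by edgeR's quasi-likelihood test, on the y axis, under 6 scalings on the x axis, for each of the 3 comparisons. At 4 h TMM gave 5561 higher and 6252 lower, and mitochondrial mRNAs as the reference gave 393 and 16573.

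After 4 h of AZD4573, mRNA of the survival factor MCL1, which encodes an anti-apoptotic BCL2-family protein (GRCh38 chromosome 1, 150574551 to 150579738), went from 323 ± 19.8 CPM in DMSO to 95.1 ± 8.55 CPM (SD, n = 3), 3.40-fold lower. HEXIM1, which encodes an inhibitory partner of P-TEFb (chromosome 17, 45148502 to 45152101), was 9.51-fold lower, at 11.5 ± 0.986 CPM against 109 ± 7.67. EGR1, an immediate early transcription factor gene (chromosome 5, 138465490 to 138469315), was 15.8-fold higher, at 87.5 ± 18.6 CPM against 5.52 ± 1.05. Of 461 zinc finger genes named ZNF, 404 were called lower and 8 higher. The directions of these 3 genes and of the ZNF median held under each of the 6 scalings.

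By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 11813 of the 19809 genes were called at 4 h, 5561 higher and 6252 lower. Of these, 1415 were higher and 3967 lower by at least 2-fold. Among the 14340 protein-coding genes tested, 4677 were called higher and 4596 lower. Library totals as the only scaling gave 2685 higher and 8599 lower, ribosomal protein mRNAs as the reference 726 and 12435, and mitochondrial mRNAs as the reference 393 and 16573, while upper-quartile scaling gave 6687 and 5431. A filter of at least 1 CPM in 3 libraries left 864 genes higher by at least 2-fold. In 68.6% of genes the 3 treated libraries did not overlap the 3 DMSO libraries, where chance gives 10%.

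Among protein-coding genes with a mean of at least 4 log2 CPM, DDIT4, a stress-induced inhibitor of mTORC1 signalling (chromosome 10, 72273920 to 72276036), fell furthest, with a log2 fold change of -5.00 ± 0.22 (SE). PHF23 (-4.31), SLITRK6 (-4.28), the splicing kinase gene CLK1 (-4.23), PNRC2 (-3.98) and MPHOSPH10 (-3.94) followed. The largest rise was in ANKRD30BL (chromosome 2, 132147591 to 132257969), from 1.24 ± 0.572 to 90.7 ± 29.2 CPM, a log2 fold change of 6.18 ± 0.30 (SE). After EGR1 (3.99) came RASL11A (3.74), the stress-responsive cytokine gene GDF15 (3.73, 238 ± 152 CPM, with a wide spread between libraries), ADAMTSL4 (3.48) and SLX1B (2.50). Adjusted p was at most 9.3e-05 for each of these genes in edgeR's test. SLX1B is uncertain, since it overlaps other genes and how reads were shared out with the near-identical SLX1A is unknown. Of 103 named genes examined, 21 had at least 10% of their exon bases covered by another gene, and with no strand stated their values are uncertain, among them DDIT4, HEXIM1, ADAMTSL4, CEBPB, FANCF, BCL2L1, JUNB, CCND1, IMP3, RRS1, MED17, RARA, REL, BTG1, GAPDH, ALDOC, COX6A1, ACTA2, PRSS8 and ZBED6.

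Of the apoptosis regulators fixed in advance, the caspase inhibitor gene XIAP was lower (-1.20 ± 0.14, SE on the log2 scale), as were BCL2 (-0.66 ± 0.11) and CFLAR (-0.44 ± 0.15), while BCL2L1, at -0.18 ± 0.10, did not pass edgeR's test (adjusted p = 0.155). The CFLAR call (edgeR adjusted p = 0.0196) was lost without DMSO replicate 1 (0.0528), DMSO replicate 3 (0.0559) or 4 h replicate 1 (0.0623), and with upper-quartile scaling (0.120). Over the 15 tested BCL2-family and IAP survival genes, 2 higher and 6 lower were called, with a median log2 fold change of -0.18 (camera adjusted p = 0.398). BIRC2, another inhibitor of apoptosis, stood at -1.04. Of the 22 pro-apoptotic BH3-only, effector and death receptor genes, 4 higher and 7 lower were called (median -0.26, camera adjusted p = 0.276). The death receptor gene TNFRSF1A (-2.75) and the BH3-only gene BMF (-1.80) were lower, and BBC3, which encodes PUMA, stood at 0.55 (edgeR adjusted p = 0.0916).

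CDK9 mRNA stood at -0.92 ± 0.14 (log2, SE), and of 38 P-TEFb, 7SK and super elongation complex genes 4 higher and 23 lower were called (median -0.51, camera adjusted p = 2.1e-04, adjusted p = 0.264 with an estimated correlation). Members with small p-values were HEXIM1 (-3.25), LEO1, a subunit of the PAF1 complex (-2.62), and the 7SK capping enzyme gene MEPCE (-2.50). Mediator, the coactivator that bridges transcription factors and the polymerase, had 3 higher and 20 lower called of 32 subunit genes (median -0.52, camera adjusted p = 0.0050, adjusted p = 0.264 with an estimated correlation), led by MED18 (-4.07) and MED17 (-2.88). For the ZNF genes, which encode zinc finger proteins, 8 higher and 404 lower (11 and 409 adjusted over the list alone) were called (median -1.82, camera adjusted p = 1.2e-39, adjusted p = 0.144 with an estimated correlation). ZNF689 changed by -4.12, ZNF281 by -3.46 and ZNF24 by -2.19. Here and for the lists that follow, a median kept its sign under each of the 6 scalings unless a change is given.

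Of 46 G2/M genes, 1 higher and 26 lower were called (median -0.48, camera adjusted p = 3.9e-04, adjusted p = 0.592 with an estimated correlation). The mitotic kinase gene AURKA went from 179 ± 5.73 to 19.6 ± 4.01 CPM (-3.19 ± 0.14 on the log2 scale, SE), with CKS2 at -2.32 and the kinetochore gene NDC80 at -2.12. Of 37 homologous recombination and Fanconi anaemia genes, 7 higher and 21 lower were called (median -0.46, camera adjusted p = 0.0189, adjusted p = 0.471 with an estimated correlation), a list call lost with the filter of 1 CPM in 3 libraries (adjusted p = 0.057). Among them were FANCF (-3.11) and XRCC2 (-2.12). Unfolded protein and integrated stress response genes had 8 higher and 17 lower (9 and 18 adjusted over the list alone) called of 28 (median -0.86, camera adjusted p = 4.7e-04, adjusted p = 0.468 with an estimated correlation). Their members with small p-values were DNAJB9 (-3.68), HERPUD1 (-2.38) and CEBPB (-3.97).

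All 77 tested cytosolic ribosomal protein genes were called higher (median 0.78 but -0.02 with the ribosomal protein reference and -0.48 with the mitochondrial reference, camera adjusted p = 2.1e-17, adjusted p = 0.468 with an estimated correlation), while the mitochondrial reference called 68 of them lower. RPS11 changed by 0.86 and RPL10A by 0.80. The 13 mitochondrially encoded mRNAs, made by a separate polymerase, were all called higher (median 1.23, below 0 with the mitochondrial reference, camera adjusted p = 1.6e-11, adjusted p = 0.318 with an estimated correlation), 12 of them with the ribosomal protein reference. MT-ND4 changed by 1.23 and MT-CO2 by 1.29. Nuclear-encoded oxidative phosphorylation genes gave 72 higher and 0 lower called of 75 (median 0.75 but -0.05 with the ribosomal protein reference and -0.50 with the mitochondrial reference, camera adjusted p = 1.2e-13, adjusted p = 0.468 with an estimated correlation), among them NDUFA10 (0.77) and COX6A1 (1.02). Glycolysis genes had 19 higher and 2 lower called of 22 (median 0.72 but -0.07 with the ribosomal protein reference and -0.54 with the mitochondrial reference, camera adjusted p = 3.9e-04, adjusted p = 0.468 with an estimated correlation), with GAPDH at 0.87 and ALDOC at 0.78. Their list call ended with the mitochondrial reference (adjusted p = 0.0928).

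Replication-dependent histone mRNAs, most of which lack a poly(A) tail, gave 22 higher and 8 lower called of 62 (median 0.42 but -0.38 with the ribosomal protein reference and -0.85 with the mitochondrial reference, camera adjusted p = 0.025, adjusted p = 0.64 with an estimated correlation). That list's camera call ended without DMSO replicate 1 (adjusted p = 0.0596) or 4 h replicate 2 (0.0685). HIST1H4C changed by 0.97 and HIST1H2BK by 0.94. Markers of fibroblast and mesenchymal cells gave 7 higher and 0 lower called of 13 (median 0.62 but -0.17 with the ribosomal protein reference and -0.59 with the mitochondrial reference, camera adjusted p = 0.0203, adjusted p = 0.468 with an estimated correlation). COL5A1 went from 27.2 ± 0.805 to 67.6 ± 14.3 CPM, COL1A1 from 24.3 ± 3.04 to 53.1 ± 9.56, and ACTA2 from 1.49 ± 0.283 to 2.83 ± 0.890. The call of this marker list was lost without DMSO replicate 1 (camera adjusted p = 0.0596), 4 h replicate 1 (0.0715) or 2 (0.0544), or 8 h replicate 2 (0.0551) or 3 (0.0602). Haematopoietic and endothelial markers gave 4 higher and 0 lower called of 11 (median 0.70, below 0 with both reference sets, camera adjusted p = 0.147).

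MYC was higher (1.24 ± 0.17, SE), at 109 ± 8.49 CPM against 46.1 ± 3.38, although with the mitochondrial reference its log2 fold change was -0.01. The AP-1 genes JUNB (2.27 ± 0.28) and FOS (2.06 ± 0.17) were higher, as was the cell cycle inhibitor gene CDKN1A (1.69 ± 0.20), whose call ended with the mitochondrial reference (edgeR adjusted p = 0.0603). MDM2, a p53-induced gene, was lower (-1.05 ± 0.21). ESR1, the estrogen receptor gene, stood at 0.34 ± 0.12 (edgeR adjusted p = 0.0215), a call lost without DMSO replicate 1 (0.0554), 2 (0.108) or 3 (0.0541), without 4 h replicate 2 (0.0852) and with no filter on low counts (0.0575). Its sign turned with library totals (-0.03), ribosomal protein mRNAs (-0.45) or mitochondrial mRNAs (-0.91) as the scaling. CCND1, the cyclin D1 gene, at -0.11 ± 0.11 (adjusted p = 0.398), and POLR2A, the largest polymerase subunit gene, at 0.05 ± 0.13 (adjusted p = 0.76), did not pass edgeR's test under TMM. With library totals and both reference sets both were called lower, CCND1 at -0.48, -0.91 and -1.37 and POLR2A at -0.31, -0.73 and -1.20. BCL2L1 was then called lower too, at -0.55, -0.97 and -1.44. CCND1 turned to 0.02 with upper-quartile scaling, and POLR2A turned below 0 without 4 h replicate 1.

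The remaining lists did not pass camera at 4 h. Immediate early genes gave 18 higher and 27 lower of 52 (median -0.82, camera adjusted p = 0.336), with KLF10 at 1.36 and BTG1 at -3.11. G1/S and DNA replication genes gave 18 higher and 21 lower (19 and 21 adjusted over the list alone) of 48 (median -0.06, above 0 with upper-quartile scaling, camera adjusted p = 0.647), with CDC25A at -2.44 and FEN1 at -0.85. Ribosome biogenesis and MYC target genes gave 16 higher and 23 lower (19 and 24 adjusted over the list alone) of 52 (median -0.08, above 0 with upper-quartile scaling, camera adjusted p = 0.276), with IMP3 at -1.96 and RRS1 at -2.07. p53 targets gave 10 higher and 17 lower (11 and 17 adjusted over the list alone) of 34 (median -0.47, camera adjusted p = 0.0751), with SESN2 at -4.49 and PPM1D at -2.74. NF-kB targets gave 8 higher and 7 lower of 23 (median 0.01, below 0 with library totals and both reference sets, camera adjusted p = 0.671), with NFKBIE at -2.46 and REL at -0.79. Estrogen receptor targets and luminal transcription factors gave 23 higher and 10 lower of 44 (median 0.34, below 0 with library totals and both reference sets, camera adjusted p = 0.0712), with TFAP2C at -2.89 and RARA at 0.82. RNA polymerase II subunits gave 7 higher and 1 lower of 12 (median 0.58, below 0 with both reference sets, camera adjusted p = 0.0769), with POLR2D at -1.02 and POLR2G at 0.73.

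Small nucleolar RNA host genes gave 5 higher and 9 lower of 21 (median -0.29, camera adjusted p = 0.0701), with SNHG3 at -1.95 and SNHG12 at -2.57. Heat shock and chaperone genes gave 8 higher and 11 lower of 28 (median -0.24, camera adjusted p = 0.243), with DNAJB1 at -3.81. Interferon-stimulated genes gave 10 higher and 8 lower of 33 (median -0.16, camera adjusted p = 0.518), with DTX3L at -1.70 and ISG20 at 1.62. The interferon list had a mean of -0.09 while camera placed it up. Cholesterol and sterol synthesis genes gave 17 higher and 8 lower (18 and 8 adjusted over the list alone) of 31 (median 0.36, below 0 with library totals and both reference sets, camera adjusted p = 0.143), with SQLE at -0.68 and INSIG2 at -2.32. Epithelial keratin and adhesion genes gave 14 higher and 4 lower (14 and 6 adjusted over the list alone) of 25 (median 0.50, below 0 with both reference sets, camera adjusted p = 0.0751), with CLDN4 at -1.79 and SPINT2 at 1.06. Nuclear-retained long noncoding RNAs gave 3 higher and 2 lower of 7 (median 0.18, below 0 with library totals and both reference sets, camera adjusted p = 0.398), with PVT1 at 1.25 and TUG1 at -0.59. Spliceosome and SR protein genes gave 22 higher and 13 lower of 48 (median 0.23, below 0 with library totals and both reference sets, camera adjusted p = 0.518), with SRSF6 at -0.78 and CLK4 at -2.40. The spliceosome list had a mean of -0.07 beside its positive median. Camera called more lists in other fits, in the direction it gave them with TMM (adjusted p at most 0.0491). With both reference sets these were the p53, ribosome biogenesis, heat shock, haematopoietic and small nucleolar RNA host lists, the last with library totals too, and with the mitochondrial one G1/S. With upper-quartile scaling and limma-voom they were the estrogen receptor, polymerase II and epithelial lists. With no filter they were these 3 and the p53, host gene, haematopoietic and pro-apoptotic lists. The fry test, of a list against no change, called all of these and the survival and immediate early lists. Single libraries left out gave calls of the p53 (8 h replicate 3, 0.0406), estrogen receptor (4 h replicate 3, 0.0200), host gene (4 h replicate 2, 0.0484) and epithelial lists (4 h replicate 3, 0.0362).

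**Figure D3:**
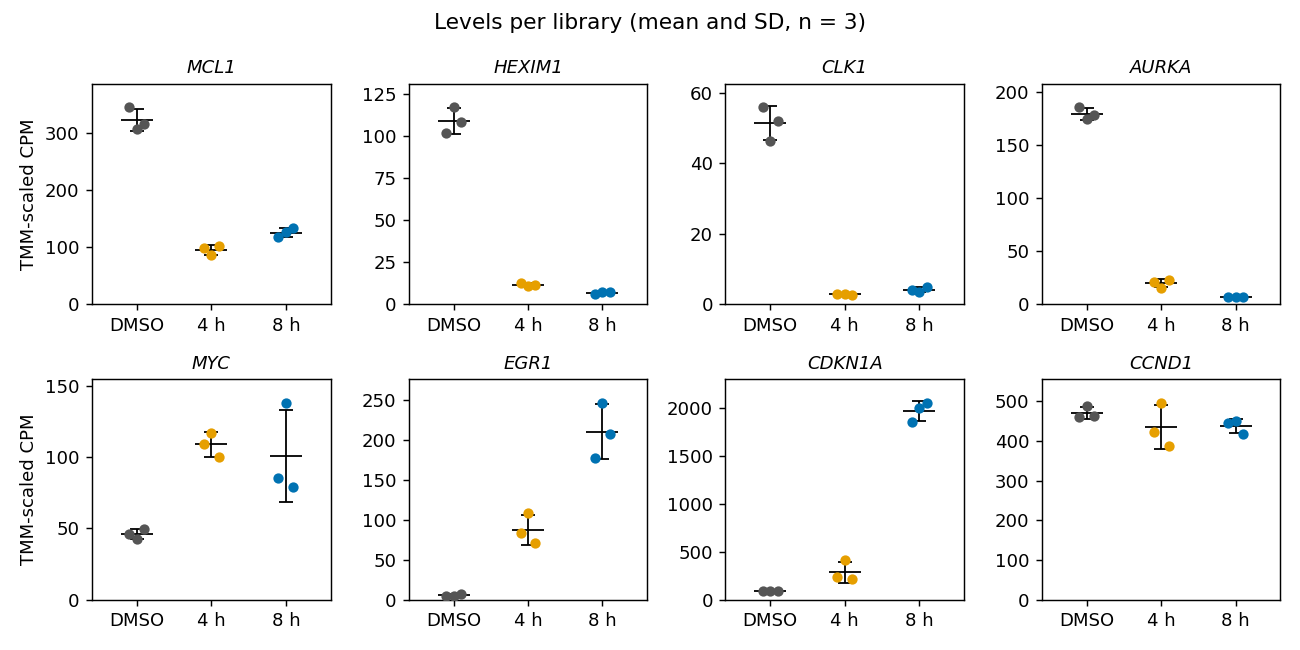
TMM-scaled CPM (y axis, from 0) of 8 genes in DMSO, at 4 h and at 8 h, one point per library, with the mean and SD of 3 libraries as a bar. MCL1 stood at 323 ± 19.8, 95.1 ± 8.55 and 125 ± 7.79 CPM.

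At 8 h CDKN1A reached 1966 ± 104 CPM from 88.9 ± 2.51 in DMSO, 22.1-fold higher, and GDF15 reached 979 ± 171 CPM from 17.9 ± 3.78 (SD, n = 3). HEXIM1 was 16.3-fold lower, at 6.71 ± 0.795 CPM, AURKA 26.3-fold lower, and MCL1 2.58-fold lower, at 125 ± 7.79 CPM, against 3.40-fold at 4 h. In edgeR's quasi-likelihood test 14285 genes were called, 6687 higher and 7598 lower, of which 3913 and 5519 by at least 2-fold.

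Of the 14340 protein-coding genes, 5408 were called higher and 5727 lower at 8 h. The split was 3541 higher and 10927 lower with library totals, 1024 and 15447 with ribosomal protein mRNAs as the reference, 711 and 16462 with mitochondrial mRNAs, and 8013 and 6376 with upper-quartile scaling. The treated and DMSO libraries did not overlap in 75.0% of genes.

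SLITRK6 showed the largest fall at 8 h, from 64.7 ± 6.24 to 0.704 ± 0.324 CPM, a log2 fold change of -6.52 ± 0.22 (SE), followed by ATXN7L3B (-5.56), PNRC2 (-5.45), TSPYL5 (-5.32), MFSD5 (-5.20) and CSTF2T (-4.94). ATXN7L3B (chromosome 12, 74537827 to 74545430), TSPYL5 (chromosome 8, 97273474 to 97277964) and CSTF2T (chromosome 10, 51695487 to 51699591) have a single exon in the annotation. ANKRD30BL, uncertain as at 4 h, was again the largest rise (6.96 ± 0.31), followed by RASL11A (5.89), GDF15 (5.77), EGR1 (5.25), ADAMTSL4 (4.99) and the glutamate receptor subunit gene GRIN2C (4.91). Adjusted p was at most 9.4e-09 for each of these genes in edgeR's test.

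Among the fixed genes, XIAP (-1.90 ± 0.14, SE), BCL2 (-0.81 ± 0.12), CFLAR (-0.84 ± 0.15) and CDK9 (-1.44 ± 0.14) were lower. BCL2L1, at -0.37 ± 0.11, was called lower by edgeR (adjusted p = 0.00599), but not with upper-quartile scaling (0.401). JUNB (3.96 ± 0.30), FOS (3.87 ± 0.17) and CDKN1A (4.47 ± 0.22) were higher. MYC stood at 1.13 ± 0.17 with TMM, and its sign turned with ribosomal protein (-0.33) or mitochondrial mRNAs (-0.57) as the reference. ESR1 stood at 0.48 ± 0.12 and turned to -0.16 with library totals, -0.95 with the ribosomal protein and -1.23 with the mitochondrial reference. MDM2, at -0.77 ± 0.21, lost its call with upper-quartile scaling (edgeR adjusted p = 0.0777). CCND1 (-0.10 ± 0.11, adjusted p = 0.403) and POLR2A (-0.16 ± 0.13, adjusted p = 0.283) did not pass edgeR's test. Library totals and both other references called them lower, CCND1 at -0.76, -1.54 and -1.82 and POLR2A at -0.82, -1.61 and -1.87, while upper-quartile scaling turned both above 0 (0.17 and 0.11). POLR2A was also called lower without 8 h replicate 2 (adjusted p = 0.0494).

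The lists called lower at 4 h were called lower again. P-TEFb, 7SK and super elongation complex genes had 7 higher and 29 lower called (median -1.36, camera adjusted p = 2.4e-06, adjusted p = 0.134 with an estimated correlation), with LEO1 at -4.78 and MEPCE at -3.55. Mediator subunits had 4 higher and 23 lower (median -0.77, camera adjusted p = 6.0e-04, adjusted p = 0.134 with an estimated correlation), with MED18 at -4.44. ZNF genes had 19 higher and 403 lower (19 and 405 adjusted over the list alone) (median -2.15, camera adjusted p = 2.0e-25, adjusted p = 0.134 with an estimated correlation), with ZNF689 at -4.81 and ZNF24 at -3.95. ZNF416 was at 0 in every 8 h library, and placing it at its bound of 3 counts over the group left that median at -2.15. G2/M genes had 4 higher and 39 lower (6 and 39 adjusted over the list alone) (median -1.03, camera adjusted p = 3.6e-08, adjusted p = 0.421 with an estimated correlation), with AURKA at -4.72. Homologous recombination and Fanconi anaemia genes had 8 higher and 26 lower (8 and 27 adjusted over the list alone) (median -0.99, camera adjusted p = 3.6e-04, adjusted p = 0.375 with an estimated correlation), with FANCF at -4.09. Unfolded protein and integrated stress response genes had 7 higher and 18 lower (8 and 18 adjusted over the list alone) (median -1.40, camera adjusted p = 0.00678, adjusted p = 0.532 with an estimated correlation), with CEBPB at -3.98. Ribosome biogenesis and MYC target genes, with 15 higher and 28 lower (median -0.62, camera adjusted p = 0.00678, adjusted p = 0.659 with an estimated correlation), were called as a list at this time, though not with limma-voom (adjusted p = 0.0603). The small ribosomal subunit processing gene IMP3 stood at -4.30.

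The lists that camera called higher at 4 h were called higher again with TMM, joined by immediate early genes and haematopoietic markers. All 77 cytosolic ribosomal protein genes were called higher (median 1.35 but -0.10 with the ribosomal protein reference and -0.36 with the mitochondrial reference, camera adjusted p = 2.0e-25, adjusted p = 0.339 with an estimated correlation), while the mitochondrial reference called 48 of them lower. Mitochondrially encoded mRNAs were all called higher (median 1.70, below 0 with the mitochondrial reference, camera adjusted p = 4.1e-11, adjusted p = 0.306 with an estimated correlation), 8 of them with the ribosomal protein reference. Oxidative phosphorylation genes had 72 higher and 0 lower called (median 1.19 but -0.25 with the ribosomal protein reference and -0.52 with the mitochondrial reference, camera adjusted p = 1.7e-17, adjusted p = 0.375 with an estimated correlation). Glycolysis genes had 16 higher and 3 lower (median 1.15 but -0.30 with the ribosomal protein reference and -0.57 with the mitochondrial reference, camera adjusted p = 1.8e-04, adjusted p = 0.421 with an estimated correlation), with GAPDH at 1.54. The glycolysis call ended with the ribosomal protein (adjusted p = 0.0591) and mitochondrial references (0.0935). Histones had 41 higher and 2 lower (median 1.14 but -0.29 with the ribosomal protein reference and -0.58 with the mitochondrial reference, camera adjusted p = 1.4e-05, adjusted p = 0.453 with an estimated correlation), with HIST1H4C at 3.14. Immediate early genes had 29 higher and 16 lower (median 0.73 but -0.70 with the ribosomal protein reference and -0.98 with the mitochondrial reference, camera adjusted p = 0.00678, adjusted p = 0.569 with an estimated correlation). KLF10 (3.22) was higher and the antiproliferative gene BTG1 (-4.71) lower.

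Fibroblast and mesenchymal markers had 10 higher and 0 lower called (median 1.55 but -0.15 with the mitochondrial reference, camera adjusted p = 9.1e-04, adjusted p = 0.339 with an estimated correlation). ACTA2 stood at 19.7 ± 3.58 CPM, COL1A1 at 85.0 ± 5.76 and COL5A1 at 98.6 ± 4.64. Haematopoietic and endothelial markers had 9 higher and 1 lower called (median 1.09 but -0.33 with the ribosomal protein reference and -0.59 with the mitochondrial reference, camera adjusted p = 0.0289, adjusted p = 0.339 with an estimated correlation). That call ended without 8 h replicate 3 (camera adjusted p = 0.0551), with upper-quartile scaling (0.0691), with DESeq2 (0.0541) and with the filter of 1 CPM in 3 libraries (0.0504). The B-cell receptor gene CD79A went from 0.114 ± 0.0369 to 9.95 ± 1.06 CPM, and the haemoglobin gene HBA1 from 2.11 ± 0.594 to 7.84 ± 1.43. Epithelial keratin and adhesion genes gave 13 higher and 6 lower (median 0.44, below 0 with library totals and both reference sets, camera adjusted p = 0.263).

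The other lists did not pass camera at 8 h. BCL2-family and IAP survival genes gave 6 higher and 8 lower (median -0.37, camera adjusted p = 0.678). Pro-apoptotic BH3-only, effector and death receptor genes gave 5 higher and 15 lower (median -0.84, camera adjusted p = 0.102), with TNFRSF1A at -4.30 and BBC3 at 3.49. RNA polymerase II subunits gave 7 higher and 2 lower (median 1.00, below 0 with both reference sets, camera adjusted p = 0.069), with POLR2D at -2.34. G1/S and DNA replication genes gave 15 higher and 26 lower (16 and 26 adjusted over the list alone) (median -0.58, camera adjusted p = 0.069), with FEN1 at -2.63. Small nucleolar RNA host genes gave 7 higher and 8 lower (median -0.08, above 0 with upper-quartile scaling and RLE, camera adjusted p = 0.696), with SNHG3 at -1.95. Heat shock and chaperone genes gave 8 higher and 16 lower (9 and 16 adjusted over the list alone) (median -0.63, camera adjusted p = 0.129), with DNAJB1 at -4.21.

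Estrogen receptor targets and luminal transcription factors gave 22 higher and 10 lower (median 0.25, below 0 with library totals and both reference sets, camera adjusted p = 0.0598), with TFAP2C at -4.46. p53 targets gave 15 higher and 14 lower (median -0.05, above 0 with upper-quartile scaling and RLE, camera adjusted p = 0.265), with SESN2 at -1.58 and PPM1D at -0.55. NF-kB targets gave 11 higher and 5 lower (median 0.40, below 0 with library totals and both reference sets, camera adjusted p = 0.401), with REL at -2.08. Interferon-stimulated genes gave 13 higher and 8 lower (median 0.22, below 0 with library totals and both reference sets, camera adjusted p = 0.401), with ISG20 at 4.12 and DTX3L at -2.54. Cholesterol and sterol synthesis genes gave 17 higher and 12 lower (median 0.65, below 0 with library totals and both reference sets, camera adjusted p = 0.265), with SQLE at -2.76 and LDLR at 1.83. Nuclear-retained long noncoding RNAs gave 4 higher and 2 lower (median 0.41, below 0 with library totals and both reference sets, camera adjusted p = 0.376), with PVT1 at 1.64. Spliceosome and SR protein genes gave 23 higher and 21 lower (median 0.19, below 0 with library totals and both reference sets, camera adjusted p = 0.876), with SRSF6 at -2.25. Camera placed the p53 list up (mean 0.31) against its negative median. The interferon list had a mean of -0.07, and SAMD9, at 0 in every 8 h library, left its median at 0.22 when placed at its bound. The spliceosome list had a mean of -0.19 and camera placed it down. Other fits called more lists at 8 h, in camera's direction with TMM (adjusted p at most 0.0430). These were the G1/S and heat shock lists with library totals, both reference sets and no filter, the spliceosome list with both reference sets, the pro-apoptotic list with these and no filter, the estrogen receptor list with RLE, upper-quartile scaling, DESeq2, the 6 libraries alone and no filter, and the polymerase II list with upper-quartile scaling, no filter and the replicate block. The fry test called all of these and the survival, host gene and long noncoding RNA lists. Without single libraries the polymerase II (8 h replicate 3, 0.0201), G1/S (4 h replicate 2, 0.0498, or 8 h replicate 2, 0.0184) and estrogen receptor lists (4 h replicate 3, 0.0374) were called.

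**Figure D4:**
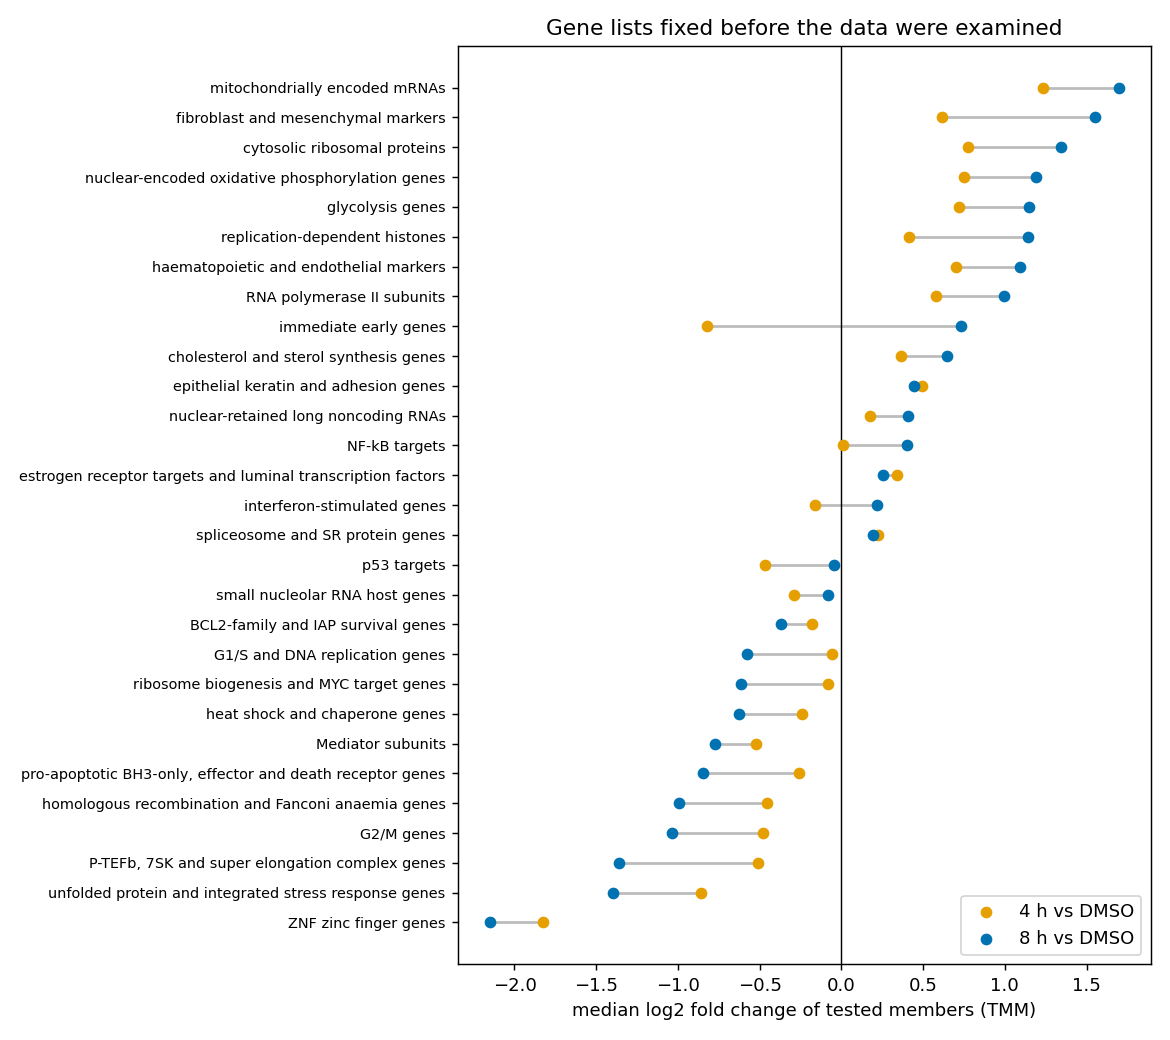
Median log2 fold change with TMM scaling (x axis) of the tested members of the 29 gene lists (y axis), at 4 h and 8 h against DMSO, joined by a line. ZNF genes stood at -1.82 and -2.15 and were below 0 under each scaling, while cytosolic ribosomal proteins stood at 0.78 and 1.35 and turned to -0.48 and -0.36 with mitochondrial mRNAs as the reference.

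Between 4 h and 8 h, CDKN1A rose a further 6.85-fold. MCL1 went from 95.1 ± 8.55 to 125 ± 7.79 CPM (log2 0.40 ± 0.11, SE, edgeR adjusted p = 0.0089). Library totals ended that call (log2 0.12, edgeR adjusted p = 0.445), and the ribosomal protein (log2 -0.26) and mitochondrial references (log2 -0.0590) turned its direction. BTG2, an antiproliferative p53-responsive gene, went from 6.52 ± 5.24 to 107 ± 48.6 CPM (4.04 ± 0.43), and the BH3-only gene BBC3 from 8.82 ± 4.90 to 67.7 ± 7.50 CPM (2.94 ± 0.27). Immediate early genes gave 37 higher and 3 lower (38 and 3 adjusted over the list alone) called of 52 under TMM, and the list median stayed above 0 under each scaling. In edgeR's test 8104 genes were called, 3673 higher and 4431 lower at 8 h than at 4 h, of which 1140 and 1323 by at least 2-fold.

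Of the protein-coding genes, 2948 were called higher and 3934 lower. The split was 1703 higher and 6931 lower with library totals, 5112 and 3446 with upper-quartile scaling, 647 and 10953 with the ribosomal protein and 758 and 8385 with the mitochondrial reference. The stricter filter left 662 genes higher by at least 2-fold. The libraries at 8 h and 4 h did not overlap in 46.7% of genes. After BTG2, the largest rises were GRIN2C (3.68), GPR157 (3.65), ID3 (3.26) and BBC3. The largest falls were DOLK (-3.25), ATXN7L3B (-3.05), the serine protease gene PRSS8 (-2.89), MFSD5 (-2.58) and ZBED6 (-2.34). ZBED6 is uncertain, since exons of ZC3H11A cover 96.0% of its exon bases on the same strand.

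By camera these lists fell from 4 h to 8 h. P-TEFb, 7SK and super elongation complex genes had 5 higher and 25 lower (5 and 26 adjusted over the list alone) (median -0.52, camera adjusted p = 3.7e-06, adjusted p = 0.154 with an estimated correlation). Mediator subunits had 3 higher and 15 lower (4 and 15 adjusted over the list alone) (median -0.36, camera adjusted p = 0.00218, adjusted p = 0.167 with an estimated correlation). G1/S and DNA replication genes had 9 higher and 23 lower (9 and 24 adjusted over the list alone) (median -0.31, camera adjusted p = 3.9e-04, adjusted p = 0.442 with an estimated correlation). G2/M genes had 3 higher and 33 lower (3 and 34 adjusted over the list alone) (median -0.62, camera adjusted p = 2.8e-11, adjusted p = 0.257 with an estimated correlation). Homologous recombination and Fanconi anaemia genes had 0 higher and 21 lower (0 and 24 adjusted over the list alone) (median -0.55, camera adjusted p = 3.5e-05, adjusted p = 0.25 with an estimated correlation). Ribosome biogenesis and MYC target genes had 6 higher and 24 lower (median -0.26, camera adjusted p = 7.3e-06, adjusted p = 0.394 with an estimated correlation). ZNF zinc finger genes had 29 higher and 166 lower (median -0.35, camera adjusted p = 0.00293, adjusted p = 0.568 with an estimated correlation). Pro-apoptotic BH3-only, effector and death receptor genes had 4 higher and 11 lower (median -0.48, camera adjusted p = 0.0492, adjusted p = 0.266 with an estimated correlation). The ZNF call was lost with the ribosomal protein reference (camera adjusted p = 0.116). The pro-apoptotic call was lost without 4 h replicate 2 (camera adjusted p = 0.202), 8 h replicate 1 (0.0645) or 8 h replicate 3 (0.111), with RLE (0.0596) or upper-quartile scaling (0.0823), with the stricter filter (0.141), in a fit of the 6 libraries alone (0.0812) and with the replicate block (0.0933).

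Camera placed these lists higher at 8 h than at 4 h. Immediate early genes had 37 higher and 3 lower (38 and 3 adjusted over the list alone) (median 1.04, camera adjusted p = 7.8e-18, adjusted p = 0.154 with an estimated correlation). p53 targets had 16 higher and 5 lower (18 and 5 adjusted over the list alone) (median 0.40 but -0.24 with the ribosomal protein reference and -0.06 with the mitochondrial reference, camera adjusted p = 8.0e-10, adjusted p = 0.154 with an estimated correlation). Cytosolic ribosomal proteins had 77 higher and 0 lower (median 0.55 but -0.10 with the ribosomal protein reference, camera adjusted p = 2.2e-21, adjusted p = 0.25 with an estimated correlation). Mitochondrially encoded mRNAs had 12 higher and 0 lower (13 and 0 adjusted over the list alone) (median 0.49 but -0.16 with the ribosomal protein reference, camera adjusted p = 6.3e-05, adjusted p = 0.389 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes had 60 higher and 0 lower (62 and 0 adjusted over the list alone) (median 0.44 but -0.21 with the ribosomal protein reference and -0.01 with the mitochondrial reference, camera adjusted p = 3.0e-12, adjusted p = 0.382 with an estimated correlation). Replication-dependent histones had 40 higher and 1 lower (median 0.85, camera adjusted p = 2.3e-09, adjusted p = 0.257 with an estimated correlation). Small nucleolar RNA host genes had 7 higher and 0 lower (6 and 0 adjusted over the list alone) (median 0.38 but -0.26 with the ribosomal protein reference and -0.07 with the mitochondrial reference, camera adjusted p = 0.0159, adjusted p = 0.229 with an estimated correlation). Glycolysis genes had 13 higher and 3 lower (15 and 3 adjusted over the list alone) (median 0.43 but -0.23 with the ribosomal protein reference and -0.03 with the mitochondrial reference, camera adjusted p = 0.00794, adjusted p = 0.522 with an estimated correlation). Fibroblast and mesenchymal markers had 8 higher and 0 lower (median 0.68, camera adjusted p = 3.9e-04, adjusted p = 0.229 with an estimated correlation). Haematopoietic and endothelial markers had 6 higher and 0 lower (median 0.76, camera adjusted p = 0.00664, adjusted p = 0.195 with an estimated correlation). The calls of mitochondrial mRNAs (0.139), glycolysis (0.57) and small nucleolar RNA host genes (0.145) ended with the ribosomal protein reference, as did those of glycolysis (0.207) and small nucleolar RNA host genes (0.0778) with the mitochondrial one and that of glycolysis with library totals (0.0506, camera adjusted p throughout). Among all 87 list results in the 3 comparisons, 45 were called by camera with its preset correlation and 0 of those with an estimated correlation. Counts over all genes and adjusted over the list alone were equal in 57 of the 87 and differed by at most 5 genes.

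Camera did not call the other lists. BCL2-family and IAP survival genes gave 5 higher and 4 lower (6 and 4 adjusted over the list alone) (median 0.07, below 0 with library totals and both reference sets, camera adjusted p = 0.658). RNA polymerase II subunits gave 7 higher and 2 lower (median 0.41, below 0 with both reference sets, camera adjusted p = 0.224). Unfolded protein and integrated stress response genes gave 6 higher and 9 lower (6 and 10 adjusted over the list alone) (median -0.28, camera adjusted p = 0.788). Heat shock and chaperone genes gave 2 higher and 13 lower (3 and 13 adjusted over the list alone) (median -0.36, camera adjusted p = 0.143). Estrogen receptor targets and luminal transcription factors gave 14 higher and 11 lower (median 0.13, below 0 with library totals and both reference sets, camera adjusted p = 0.214). NF-kB targets gave 8 higher and 3 lower (median 0.24, below 0 with library totals and both reference sets, camera adjusted p = 0.224). Interferon-stimulated genes gave 7 higher and 5 lower (median 0.17, below 0 with library totals and both reference sets, camera adjusted p = 0.412). Cholesterol and sterol synthesis genes gave 9 higher and 9 lower (10 and 9 adjusted over the list alone) (median 0.04, below 0 with library totals and both reference sets, camera adjusted p = 0.972). Epithelial keratin and adhesion genes gave 7 higher and 9 lower (8 and 9 adjusted over the list alone) (median -0.05, above 0 with upper-quartile scaling and RLE, camera adjusted p = 0.788). Nuclear-retained long noncoding RNAs gave 3 higher and 1 lower (median 0.23, below 0 with library totals and both reference sets, camera adjusted p = 0.494). Spliceosome and SR protein genes gave 8 higher and 16 lower (9 and 16 adjusted over the list alone) (median -0.06, above 0 with upper-quartile scaling, camera adjusted p = 0.227). The sterol list had a mean of -0.09 beside its positive median. Camera called the heat shock and spliceosome lists lower with library totals, both reference sets and no filter, and fry did too (adjusted p at most 0.0462), and the epithelial list lower with the ribosomal protein reference (0.0382). It called the heat shock list without 8 h replicate 2 (0.0424) and the polymerase II subunits without 8 h replicate 3 (0.0284).

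Of the genes called against DMSO, 5034 were higher at both times and 5730 lower at both, where independent lists would share 1877 and 2398. Only 56 genes were called in opposite directions, 23 higher at 4 h and lower at 8 h and 33 the reverse, while 993 were called at 4 h alone and 3465 at 8 h alone, a difference that being called does not itself test. Across genes, which are not independent replicates, log2 fold changes at the 2 times had a Pearson correlation of 0.887, which was 0.675 with no filter on low counts, and a Spearman correlation of 0.897. Simulated unchanged groups against a shared simulated DMSO group gave 0.439 and 0.424 and shared 0 calls. The 3 DMSO libraries cannot be split into parts of 2, so part of the excess over independent lists may come from the shared controls. The covariance was 2.01 against a simulated 0.0539, a difference of 1.95. Library totals left 2350 genes higher at both times, the ribosomal protein reference 575 higher and 12210 lower, and the mitochondrial reference 332 and 15747.

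Genes with a single exon, which need no splicing, were lower as a set. Of 308 protein-coding genes with a single exon in every annotated transcript, 69 higher and 157 lower (76 and 160 adjusted over the list alone) were called at 4 h, with a median log2 fold change of -0.64 (camera adjusted p = 2.4e-06, and adjusted p = 0.028 with an estimated correlation). At 8 h 103 higher and 156 lower (104 and 157 adjusted over the list alone) were called (median -0.89, camera adjusted p = 0.00227, adjusted p = 0.0844 with an estimated correlation), and between the times 88 higher and 85 lower (92 and 87 adjusted over the list alone) (median -0.01, above 0 with upper-quartile scaling and RLE, camera adjusted p = 0.81). The medians at 4 h and 8 h were below 0 under each scaling, and the 8 h call was lost with the ribosomal protein (adjusted p = 0.123) or mitochondrial reference (0.329) and with limma-voom (0.104).

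Gene length was examined through the 1434 longest protein-coding genes, spanning at least 169234 bp, and the 1434 shortest, spanning at most 5465 bp. The longest set gave 471 higher and 267 lower (457 and 259 adjusted over the list alone) at 4 h (median 0.16 but -0.20 with library totals, -0.62 with the ribosomal protein reference and -1.09 with the mitochondrial reference, camera adjusted p = 0.00692, adjusted p = 0.426 with an estimated correlation). That call ended with the ribosomal protein (0.0805) and mitochondrial references (camera adjusted p = 0.403). At 8 h the longest set gave 486 higher and 454 lower (481 and 448 adjusted over the list alone) (median 0.03, below 0 with library totals and both reference sets, mean -0.01, camera adjusted p = 0.242), and from 4 h to 8 h 159 higher and 398 lower (154 and 396 adjusted over the list alone) (median -0.13, above 0 with upper-quartile scaling, camera adjusted p = 0.117). Between the times it was called lower without 8 h replicate 3 (camera adjusted p = 0.0200), with the ribosomal protein (0.0251) or mitochondrial reference (0.0116), with limma-voom (0.0408) and with no filter (5.3e-05). For the shortest set the calls were 615 higher and 424 lower (625 and 427 adjusted over the list alone) at 4 h (median 0.32, below 0 with library totals and both reference sets, mean -0.15, camera adjusted p = 0.507). At 8 h they were 751 higher and 437 lower (755 and 441 adjusted over the list alone) (median 0.66 but -0.77 with the ribosomal protein reference and -1.05 with the mitochondrial reference, camera adjusted p = 0.0196, adjusted p = 0.646 with an estimated correlation), a list call lost with the ribosomal protein reference (adjusted p = 0.0898). From 4 h to 8 h they were 562 higher and 218 lower (595 and 231 adjusted over the list alone) (median 0.36 but -0.28 with the ribosomal protein reference and -0.09 with the mitochondrial reference, camera adjusted p = 3.8e-05, adjusted p = 0.735 with an estimated correlation).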

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

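The test of the ribosomal protein scaling given here was chosen after the result was seen. Each value below is the log2 fold change from 4 h to 8 h under TMM, or a list's median of it, which is the difference between both DMSO comparisons. A result is listed because edgeR's test (or camera, for a list) of that difference passed at an adjusted p under 0.05.

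Genes further from DMSO at 8 h in the direction of a rise were CDKN1A (2.78), GRIN2C (3.68), RASL11A (2.15), GDF15 (2.04), FOS (1.81), JUNB (1.70), ADAMTSL4 (1.51), EGR1 (1.26) and ANKRD30BL (0.79). Further falls were those of ATXN7L3B (-3.05), MFSD5 (-2.58), SLITRK6 (-2.24), CSTF2T (-2.12), TSPYL5 (-1.91), PNRC2 (-1.47), MPHOSPH10 (-0.97), HEXIM1 (-0.77), XIAP (-0.70), CDK9 (-0.51) and CFLAR (-0.40). DDIT4 (1.24), CLK1 (0.55), PHF23 (0.41) and MCL1 (0.40), all lower than in DMSO at 4 h, moved back toward it with TMM. ANKRD30BL, CLK1, PHF23 and MCL1 lost that call with library totals and both references. MCL1 turned to -0.26 and PHF23 to -0.23 with the ribosomal protein reference and to -0.0590 and -0.0455 with the mitochondrial one, and CLK1 to -0.0864 with the ribosomal protein reference alone. Among the 9 libraries left out in turn, PHF23 was called in the absence of 8 h replicate 1 alone (log2 0.30 to 0.48 without the others). CFLAR was called in the absence of 8 h replicate 3 alone (log2 -0.43 to -0.27 without the others). CFLAR also lost its call with RLE (edgeR adjusted p = 0.0714), upper-quartile scaling (0.229), the filter of 1 CPM in 3 libraries (0.0779), DESeq2 (0.0619) and the 6 libraries alone (0.0932), PHF23 with no filter (0.114), limma-voom (0.0937), the replicate block (0.0658) and the 6 libraries alone (0.125), and CLK1 with the 6 alone (0.0507). ANKRD30BL was not called without 4 h replicate 1 (0.67) or 3 (0.65), nor CLK1 without 4 h replicate 3 (0.48) or 8 h replicate 3 (0.40).

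Lists further down at 8 h were G2/M (-0.62), homologous recombination (-0.55), P-TEFb (-0.52), pro-apoptotic (-0.48), Mediator (-0.36), ZNF (-0.35), G1/S (-0.31) and ribosome biogenesis genes (-0.26). With an estimated correlation each of these calls was lost (adjusted p from 0.154 to 0.568), as was each of those below (0.154 to 0.522). The pro-apoptotic call was lost without 4 h replicate 2 (camera adjusted p = 0.202), 8 h replicate 1 (0.0645) or 8 h replicate 3 (0.111). Lists that stood higher were immediate early genes (1.04), histones (0.85), haematopoietic (0.76) and fibroblast markers (0.68) and ribosomal proteins (0.55), each above 0 under each scaling but that by the ribosomal proteins themselves (-0.0969 for that list). Mitochondrial mRNAs (0.49) turned with the ribosomal protein reference (-0.16), and oxidative phosphorylation genes (0.44), glycolysis genes (0.43), p53 targets (0.40) and small nucleolar RNA host genes (0.38) turned with both references.

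Ribosomal protein mRNAs stood above DMSO at 4 h with TMM (median 0.78, 77 of 77 called higher). The mitochondrial reference put the median at -0.48 and called 68 of them lower, a change that the choice of reference makes by construction, so their direction rests on the scaling. Whether they rose per cell or fell less than other mRNAs stays open, since these counts are relative and the amount of RNA per cell was not measured. An effect of the drug on their level is likewise untested.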

How the results depend on the processing

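The single-exon sets without histones and matched to multi-exon genes were alternatives chosen after the data were seen, and every other alternative below was planned. For list results, 1875 of 2118 alternative fits kept direction and side of the threshold, 89 lost a call, 96 gained one and 58 turned, and 0 of the turned ones were called in either fit. For named genes the numbers were 1617 of 1700, with 49 lost, 13 gained and 21 turned. List values below are the list's median minus that of all genes, so a scaling that moves every gene alike leaves them nearly alone, and the direction that can turn is camera's or fry's. The cause of each change was not tested, apart from the scalings, whose construction moves all genes of a library together, and the filters, which change the genes tested.

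Scaling by library totals gave these counts of genes: called higher 2685 (4 h), 3541 (8 h) and 1703 (8 h vs 4 h), called lower 6931 (8 h vs 4 h), higher by at least 2-fold 753 (4 h), 1523 (8 h) and 727 (8 h vs 4 h), lower by at least 2-fold 8338 (8 h) and 2766 (8 h vs 4 h), higher at both times 2350. It turned the direction of ESR1 -0.0279 (4 h) and -0.16 (8 h), POLR2A -0.31 (4 h), spliceosome 0.25 (4 h), sterol 0.0362 (8 h vs 4 h), single-exon 0.0139 (8 h vs 4 h).

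The ribosomal protein reference gave these counts of genes: called higher 726 (4 h), 1024 (8 h) and 647 (8 h vs 4 h), called lower 12435 (4 h), 15447 (8 h) and 10953 (8 h vs 4 h), higher by at least 2-fold 505 (4 h), 754 (8 h) and 441 (8 h vs 4 h), lower by at least 2-fold 8198 (4 h), 12694 (8 h) and 5764 (8 h vs 4 h), higher at both times 575, lower at both times 12210. It turned the direction of ESR1 -0.45 (4 h) and -0.95 (8 h), POLR2A -0.73 (4 h), spliceosome 0.25 (4 h), MYC -0.33 (8 h), sterol 0.71 (8 h) and 0.0331 (8 h vs 4 h), epithelial 0.52 (8 h), PHF23 -0.23 (8 h vs 4 h), CLK1 -0.0864 (8 h vs 4 h), MCL1 -0.26 (8 h vs 4 h), survival 0.0843 (8 h vs 4 h), estrogen receptor 0.14 (8 h vs 4 h), long noncoding RNA 0.25 (8 h vs 4 h), single-exon 0.0236 (8 h vs 4 h). It ended the call of longest genes 0.18 (4 h), single-exon -0.81 (8 h), shortest genes 0.74 (8 h). It added a call for longest genes -0.12 (8 h vs 4 h).

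The mitochondrial reference gave these counts of genes: called higher 393 (4 h), 711 (8 h) and 758 (8 h vs 4 h), called lower 16573 (4 h), 16462 (8 h) and 8385 (8 h vs 4 h), higher by at least 2-fold 335 (4 h), 611 (8 h) and 549 (8 h vs 4 h), lower by at least 2-fold 12114 (4 h), 14200 (8 h) and 4009 (8 h vs 4 h), higher at both times 332, lower at both times 15747. It turned the direction of MYC -0.0128 (4 h) and -0.57 (8 h), ESR1 -0.91 (4 h) and -1.23 (8 h), POLR2A -1.20 (4 h), estrogen receptor 0.37 (4 h), 0.33 (8 h) and 0.14 (8 h vs 4 h), sterol 0.39 (4 h), 0.74 (8 h) and 0.0571 (8 h vs 4 h), epithelial 0.53 (4 h) and 0.52 (8 h), long noncoding RNA 0.19 (4 h) and 0.48 (8 h), spliceosome 0.24 (4 h), longest genes 0.12 (8 h), PHF23 -0.0455 (8 h vs 4 h), MCL1 -0.0590 (8 h vs 4 h), survival 0.0839 (8 h vs 4 h), single-exon 0.0112 (8 h vs 4 h). It ended the call of longest genes 0.19 (4 h), single-exon -0.81 (8 h). It added a call for longest genes -0.12 (8 h vs 4 h).

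Upper-quartile scaling turned the direction of CCND1 0.0215 (4 h) and 0.17 (8 h), POLR2A 0.11 (8 h), spliceosome 0.28 (8 h), epithelial -0.0347 (8 h vs 4 h). RLE turned the direction of spliceosome 0.28 (8 h). Dropping the filter on low counts turned the direction of longest genes 0.0128 (8 h), sterol 0.0197 (8 h vs 4 h). It added a call for longest genes -0.14 (8 h vs 4 h). The Pearson correlation of both effects was then 0.68. A filter of 1 CPM in 3 libraries gave these counts of genes: higher by at least 2-fold 864 (4 h) and 662 (8 h vs 4 h). It turned the direction of NF-kB -0.45 (4 h), spliceosome 0.33 (8 h), epithelial 0.00532 (8 h vs 4 h).

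The limma-voom fit turned the direction of spliceosome 0.29 (8 h), single-exon 0.0118 (8 h vs 4 h). It ended the call of single-exon -0.81 (8 h). It added a call for longest genes -0.11 (8 h vs 4 h). Fitting only the libraries compared turned the direction of spliceosome 0.30 (8 h), sterol 0.0382 (8 h vs 4 h), single-exon 0.21 (8 h vs 4 h). Asking for at least 2-fold in the overlap gave these counts of genes: higher at both times 1304, lower at both times 3548. Fry tests a list against no change and not against other genes, so it does not test these values. Its direction differed for NF-kB 0.0359 (4 h), interferon -0.14 (4 h), spliceosome 0.25 (4 h), sterol 0.0523 (8 h vs 4 h), shortest genes 0.34 (4 h), longest genes 0.12 (8 h). It did not call longest genes 0.19 (4 h), shortest genes 0.74 (8 h). It called single-exon 0.00917 (8 h vs 4 h, placed lower), longest genes -0.11 (8 h vs 4 h). Camera with an estimated correlation ended the call of longest genes 0.19 (4 h), single-exon -0.81 (8 h), shortest genes 0.74 (8 h) and 0.38 (8 h vs 4 h). Matching single-exon genes without histones to multi-exon genes gave -0.38 for 8 h vs 4 h (-0.30 without matching), where the whole set was not called. DESeq2 called 5766 higher and 5737 lower at 4 h, 7023 and 6911 at 8 h, and 4145 and 3951 for 8 h vs 4 h.

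With the replicate number of the labels as a block, 5470 genes were called higher and 6186 lower at 4 h, 6580 and 7525 at 8 h, and 3640 and 4369 for 8 h vs 4 h. Deviations of same-numbered libraries correlated at -0.223 to 0.101, and 3 of 9 pairs best with their own number. With 3 libraries per group, pairing stays unknown. Under the block the sterol list turned (8 h vs 4 h, 0.0465), the pro-apoptotic list and PHF23 were not called for 8 h vs 4 h, and the polymerase II list was called at 8 h (adjusted p = 0.0399).

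Leaving out each of the 9 libraries in turn gave ranges, listed for 4 h, 8 h and 8 h vs 4 h. Genes called higher were 4718 to 6062, 6354 to 6934 and 2551 to 3998. Called lower were 5711 to 6688, 7221 to 7850 and 3597 to 4605. Higher by at least 2-fold were 1145 to 1691, 3934 to 4143 and 961 to 1547. Lower by at least 2-fold were 3893 to 4154, 5448 to 5786 and 1105 to 1667. Higher at both times were 4369 to 5337, and lower 5282 to 6023. The Pearson correlation ran from 0.817 (without 4 h replicate 2) to 0.888. The named genes and lists whose call or direction changed, and the sets of gene structure, ranged as follows: CFLAR -0.51 to -0.41 (4 h) and -0.62 to -0.27 (8 h vs 4 h), ESR1 0.26 to 0.39 (4 h), POLR2A -0.00493 to 0.0981 (4 h) and -0.29 to -0.0147 (8 h), epithelial 0.39 to 0.62 (4 h) and -0.0978 to 0.0674 (8 h vs 4 h), estrogen receptor 0.31 to 0.41 (4 h) and 0.28 to 0.49 (8 h), fibroblast 0.49 to 0.78 (4 h), longest genes 0.17 to 0.22 (4 h), -0.14 to -0.0938 (8 h vs 4 h) and 0.0796 to 0.16 (8 h), p53 -0.48 to -0.42 (4 h), histone 0.25 to 0.63 (4 h), shortest genes 0.25 to 0.42 (4 h), 0.29 to 0.46 (8 h vs 4 h) and 0.68 to 0.85 (8 h), single-exon -0.64 to -0.59 (4 h), -0.0710 to 0.0297 (8 h vs 4 h) and -0.82 to -0.67 (8 h). The rest ranged as small nucleolar RNA host -0.39 to -0.21 (4 h), ANKRD30BL 0.64 to 1.08 (8 h vs 4 h), CLK1 0.40 to 0.66 (8 h vs 4 h), PHF23 0.30 to 0.52 (8 h vs 4 h), polymerase II 0.29 to 0.57 (8 h vs 4 h) and 0.96 to 1.28 (8 h), sterol -0.0136 to 0.18 (8 h vs 4 h), heat shock -0.37 to -0.26 (8 h vs 4 h), pro-apoptotic -0.55 to -0.38 (8 h vs 4 h), unfolded protein -0.37 to -0.10 (8 h vs 4 h), G1/S -0.62 to -0.39 (8 h), haematopoietic 1.00 to 1.46 (8 h), spliceosome 0.24 to 0.38 (8 h). The calls that this ended or added are given with each result. The directions that turned were those of POLR2A without 4 h replicate 1 (4 h), of the spliceosome list without 8 h replicate 3 (8 h) and, for 8 h vs 4 h, of the sterol list (without all libraries in turn but 4 h replicate 1 and 8 h replicate 3), the epithelial list (4 h replicate 2, 8 h replicate 3), the unfolded protein list (4 h replicate 2, 8 h replicate 2) and the single-exon set (4 h replicate 2), none of them called.

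Each comparison of 3 with 3 libraries has 10 splits, too few for a share under 0.05. In fits of the 6 libraries alone, only the real split reached its own count (1 of 10 in each comparison), with 12407, 14156 and 6949 genes called at 4 h, 8 h and 8 h vs 4 h, against at most 0, 0 and 1 in another split. On counts simulated at these depths, which were not varied by themselves, 26.9% of 1.5-fold changes were called at 4 h, 28.4% at 8 h and 26.9% for 8 h vs 4 h.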

Other observations

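The tests of single-exon genes and of poly(A) selection below were chosen after the result was seen, and the search for shared sequence was planned before its outcome was known. Antisense RNA genes gave 51 called higher and 163 lower of 461 at 4 h by edgeR (median -0.33, against 0.05 over 14340 protein-coding genes), and 81 higher and 174 lower at 8 h, and their median was below 0 under each scaling. Long intergenic noncoding RNA genes gave 56 higher and 106 lower of 373 at 4 h (median -0.21) and 81 and 120 at 8 h (median -0.25, but 0.03 with upper-quartile scaling). Processed pseudogenes gave 70 higher and 55 lower of 230 at 4 h (median 0.27, but -0.10 with library totals, -0.52 with the ribosomal protein and -0.98 with the mitochondrial reference). The strand setting of the counts is not given in the sources used here, so reads of an antisense gene and its partner cannot be separated, and pseudogenes can take reads from their parent genes.

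Among the largest rises were 5 loci that are not protein-coding in the annotation, singled out after their values were seen. MIR663AHG (GRCh38 chromosome 20, 26186920 to 26251526) went from 1.93 ± 0.721 CPM in DMSO to 189 ± 86.5 at 4 h and 333 ± 37.4 at 8 h (SD, n = 3). MIR3648-1 (chromosome 21, 8208473 to 8208652) went from 0.639 ± 0.339 to 60.4 ± 12.4 and 151 ± 31.0 CPM, MIR3687-1 from 0.0886 to 17.8 and 38.1, LINC00273 (chromosome 16, 34158585 to 34160036) from 0.515 to 53.5 and 111, and AL353644.4 from 0.303 to 39.8 and 99.8. With the protein-coding gene ANKRD30BL, their log2 fold changes at 4 h ran from 6.18 to 7.58. MIR3648-1 and MIR3687-1 are known to lie within ribosomal DNA units, and precursor rRNA counted at all 6 is a candidate source. An alignment of 116 bases at 93.1% identity joined 2 of the 6, MIR663AHG and LINC00273, and none matched the 54 annotated rRNA transcripts. This leaves shared sequence open, since the reference holds no precursor rRNA and AL353644.4 has no transcript in it. Less complete poly(A) selection may also raise such RNAs, and the other 20 RNAs without a tail had a median of 1.21 at 4 h (quartiles -0.05 to 2.81, 10 higher and 1 lower) and 2.28 at 8 h, with RNU1-1 equal to RNU1-3 and RNU1-2 to RNU1-4 in every value and so not independent. Histone mRNAs had a median of 0.42 at 4 h. The median of the 20 and the most abundant, RN7SK (-1.57 ± 1.06, SE) and RN7SL1 (-2.49 ± 0.77), lay below the loci. RNU6-1 (8.41 ± 1.62) was near the floor. Such selection is not excluded. A change in the RNAs made under the drug stays open and untested.

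Single-exon protein-coding genes were lower at 4 h as a set, and GC content, transcript length or expression level might have set that difference. Against multi-exon genes matched on all of these, 262 single-exon genes other than histones stood at a median difference of -0.73 (95% bootstrap interval -1.03 to -0.52, 66.0% of genes below their matches). The interval lies below 0, so a difference remained after matching. How close the matches were was not checked, so remaining differences in these properties are not excluded. At 8 h the difference was -1.14 (-1.53 to -0.78), and from 4 h to 8 h -0.38 (-0.48 to -0.15). Leaving out histones carried part of this: unmatched medians were -0.99, -1.43 and -0.30 for these genes and -0.64, -0.89 and -0.01 for the whole set. Genes are not independent replicates, so the interval covers the choice of genes and not the spread between libraries. Shorter mRNA half-lives, which these data do not measure, and an effect of the drug on genes that need no splicing stay open as hypotheses.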
